A study of Drosophila melanogaster with 8 samples.

How the data were processed

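The series profiled nucleosomes in Drosophila S2 cells, a hemocyte-like line, before and after heat-killed Salmonella typhimurium, a Gram-negative bacterium, was added to the culture. Chromatin was crosslinked with formaldehyde and digested with micrococcal nuclease (MNase), and the mononucleosomal gel band was sequenced as 50 bp read pairs, per the labels' protocols. There were 4 groups of 2 libraries each, taken at 0, 0.5, 1 and 4 h and lettered A and B in the labels. The labels do not say what the letter marks or whether the libraries came from separate cultures, so every p-value measures only the spread between these libraries, which may be technical.

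The deposited files list sequenced fragments by chromosome, start and end, with no count, score or signal column. Reads were processed with cutadapt 1.7 and Bowtie2 2.1.0 against the build dm3, per the submitters' processing notes. Mapping options, quality filters and the handling of duplicates are not given in the sources used here. Identical fragments were present and made up between 1.51% and 6.96% of a library. The files held fragments on the arms 2L, 2R, 3L, 3R and X, on chromosome 4, on 6 heterochromatin scaffolds and on the mitochondrial genome. All coordinates are 1-based in that build.

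Fragment midpoints were counted here in 10 kb tiles of the whole genome. Tiles with a mean of at least 10 midpoints were tested with limma 3.58.1 in R 4.3.3, using voom precision weights, library sizes taken from the 5 arms, and all 8 libraries in 1 fit with 4 residual degrees of freedom. The threshold was a Benjamini-Hochberg adjusted p of 0.05. Sets of tiles by chromosome were tested with limma's fry, and with camera using an estimated correlation. These chromosome set tests were outside the plan, which named camera and fry for gene lists only. A count model had been planned only for files of deposited counts. These files list fragments, and the model was not run on the midpoints counted here. The rule for naming tiles took the 5 largest rises and the 5 largest falls past the threshold that had the same direction in A and B. Where fewer than 5 passed, a fallback written for promoters, the 6 smallest p-values in each direction, was applied to tiles as well. At 0.5 and 1 h only the first tile in each direction is named and the others are given as ranges.

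Fragment length, chromosome shares and nucleosome repeat length were computed per library with Python 3.11.15, numpy 2.4.6 and scipy 1.17.1. An exact comparison, two-sided, of 2 libraries against 2 cannot give a p below 0.333. A pair of exact permutation tests was therefore added after the data were seen. The first asks whether libraries of 1 time resemble each other, over the 105 ways to pair 8 libraries (smallest p 0.00952), and the second whether A and B follow the same course, over 24 orders of the times (smallest p 0.0417). Both were one-sided and were adjusted over 11 values. Intervals on shares are 95% Wilson intervals and cover counting error only.

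The repeat length was the slope of the first 4 peaks of the autocorrelation of midpoints on the 5 arms, smoothed over 31 bp. A first version searched for peaks in windows fixed around multiples of 178 bp. On simulated arrays of known spacing it missed by up to 16.8 bp, because the windows pulled the slope toward their own spacing. It was replaced, after its result on the libraries had been seen, by a search from 130 to 230 bp beyond the preceding peak, which missed by at most 0.3 bp on dense simulations and 4.7 bp on sparse ones. Both versions gave the same p over time, and the first version is kept among the alternatives.

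Further measurements were chosen after the data were seen. Gaps were stretches of 100 to 400 bp where coverage by 120 to 180 bp fragments was at most 10% of the local 2 kb mean. They were found in the 0 h library of 1 letter and measured in the libraries of the other letter, so that no library was measured on gaps it had defined. Correlations between maps used 120 to 180 bp fragments on the arms, with identical fragments counted once unless said otherwise. They were computed in 1 kb bins with the Poisson variance removed, with standard errors from 200 bootstrap draws of 1 Mb blocks. On simulated maps of known correlation the largest error was 0.0219.

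The tile test was tested on simulated data in which 200 tiles were changed, with each time point's own spread. At 0.5 h it recovered 98% of tiles changed by 1.5-fold, at 1 h 96% and at 4 h 64%. At 4 h it also made up to 42 false calls among 12771 tiles, against at most 4 at 0.5 h and 11 at 1 h. The 4 h libraries had the largest spread and the fewest fragments, and which of these lay behind the false calls was not tested. The false calls arose with 200 tiles changed, so they give no rate for the real libraries.

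Promoter tests, gene lists, the ratio of depletion at transcription start sites and correction for base composition had been planned. They were not run, because they need an annotation or genome of the build of the files, and neither was used here. The alternatives were other normalisations and count filters, identical fragments counted once, 120 to 180 bp fragments, thinning to the smallest library, limma without precision weights, a replicate block, fitting only the groups compared, other tile sizes, and leaving out each library in turn. The tests, their alternatives and the rule for naming tiles were fixed before the data were examined, except those said in this report to have been added, to be outside the plan or to have been chosen later.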

Results

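Nucleosome-sized fragments were mapped in S2 cells at 0 h, without stimulation, and at 0.5, 1 and 4 h after heat-killed Salmonella typhimurium was added, with 2 libraries (A and B) at each time. The question addressed was whether nucleosome occupancy changed in these immune-like cells over the hours after stimulation. The 8 libraries held 49532966 fragments. Depth fell with time in both replicates. Replicate A held 17961629 fragments at 0 h, 8548774 at 0.5 h, 4384660 at 1 h and 1638606 at 4 h. Replicate B held 9502339, 4254115, 2833098 and 409745 fragments at the same times. The largest library was 43.8 times the smallest.

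Median fragment length was lower in the later libraries, without passing a test over time. The median length on the arms was 140 ± 2.83 bp at 0 h (SD, n = 2), 135.5 ± 7.78 bp at 0.5 h, 126 ± 8.49 bp at 1 h and 123 ± 2.83 bp at 4 h. Fragments under 90 bp, shorter than the DNA of a whole nucleosome, made up 7.53% ± 0.39 at 0 h, 9.20% ± 3.40 at 0.5 h, 16.3% ± 3.21 at 1 h and 17.9% ± 1.87 at 4 h (SD, n = 2). The share of 120 to 180 bp was 59.2% ± 3.31 at 0 h and 46.5% ± 0.54 at 4 h. The share under 120 bp, the planned measure of short fragments, was 28.9% ± 1.22 at 0 h and 46.8% ± 1.85 at 4 h and was not tested. Libraries of 1 time were not shown to resemble each other beyond chance in these lengths (exact permutation p = 0.171 for the median and 0.0762 for the share under 90 bp, both adjusted p = 0.367). No value could pass this test alone after adjustment over 11 values, so it cannot show that a difference was absent. The median was 121 and 125 bp in the 4 h libraries A and B, below 142 and 138 bp at 0 h. The share under 90 bp was 16.5% and 19.2%, above 7.81% and 7.26% at 0 h. At 0.5 h the median was 141 bp in A, near its 0 h library, and 130 bp in B.

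**Figure D1:**
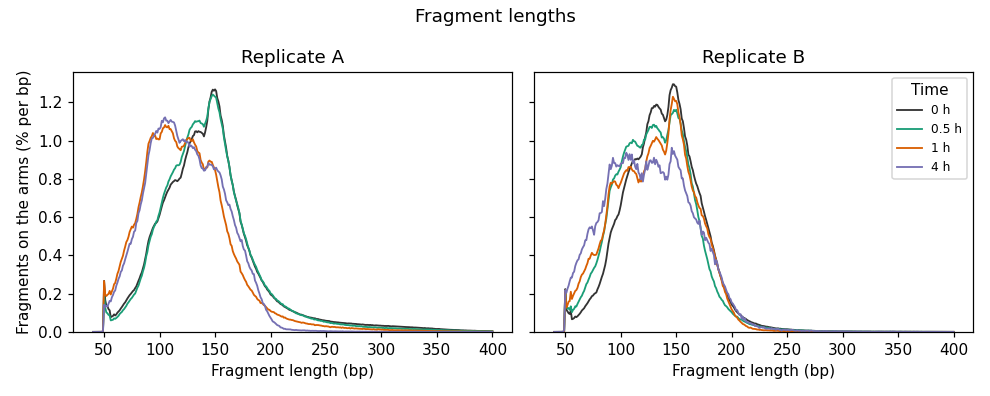
Percent of fragments on the arms (y axis) at each fragment length in bp (x axis), with 1 line per time and 1 panel per replicate. Every stimulated library except A at 0.5 h holds more fragments under 90 bp than the 0 h library of its letter.

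The arms X, 2L, 2R, 3L and 3R kept similar shares of the fragments at all times. X held 13.1% ± 0.38 of the arm total at 0 h and 12.8% ± 0.05 at 4 h (SD, n = 2), and its density was 0.665 and 0.634 of that of the autosomal arms in the 0 h libraries A and B. The heterochromatin scaffolds held 9.03% ± 0.66 relative to the arm total at 0 h, 9.37% ± 1.34 at 0.5 h, 8.32% ± 1.40 at 1 h and 9.25% ± 0.82 at 4 h. As a share of all fragments, the scaffolds at 1 h were −0.588 points from 0 h, but 0.106 points above it with identical fragments counted once and 0.244 points above it without the 1 h library B. At 4 h they were 0.0668 points above 0 h, and 1.09 points with identical fragments counted once. That setting removed 6.96% of the 0 h library A, the deepest, and 1.51% of the 4 h library B, the shallowest. On the scaffold XHet these libraries held 2474 and 49.1 fragments per kb. Differences under that setting are therefore not independent of depth. Chromosome 4, the small and largely heterochromatic autosome, was at 1.06% ± 0.02 at 0 h, 1.14% ± 0.07 at 0.5 h, 1.05% ± 0.05 at 1 h and 1.22% ± 0.17 at 4 h. The higher 4 h value came from library A, at 1.34%, against 1.10% in B. No difference between times in these shares was detectable beyond the spread between libraries (exact permutation p = 0.609 for X, 0.743 for the scaffolds and 0.2 for chromosome 4). The scaffold share was higher in every A library (9.31% to 10.3%) than in every B library (7.34% to 8.67%), and this test left that difference in the spread. The test of whether A and B followed the same course, which takes it out, gave an exact permutation p of 0.208 for the scaffolds (adjusted p = 0.327).

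The mitochondrial genome took 0.189% of fragments in A and 0.156% in B at 0 h. It took 0.0731% (95% Wilson interval 0.0706 to 0.0757) in A and 0.096% (0.0925 to 0.0997) in B at 1 h, below both 0 h libraries. At 4 h it took 2.61% (2.59 to 2.64) in A and 0.201% (0.188 to 0.215) in B, both above the 0 h libraries but far apart from each other. At 0.5 h the values were 0.283% in A and 0.136% in B. The exact permutation p over time, computed on the log2 of these shares, was 0.181 (adjusted p = 0.367).

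**Figure D2:**
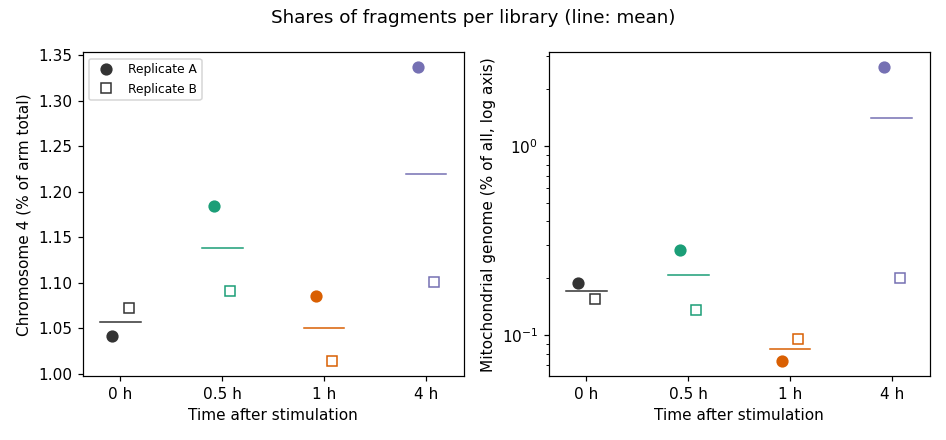
Fragments on chromosome 4 as a percent of the arm total (left) and on the mitochondrial genome as a percent of all fragments on a log axis (right), by time in h. Each point is 1 library and each line the mean of 2. Library A at 4 h is the highest in both panels, at 1.34% and 2.61%.

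The first 4 autocorrelation peaks lay at 177, 357, 539 and 709 bp in the 0 h library A and at 173, 359, 532 and 701 bp in B. The repeat length was 176.8 ± 1.48 bp at 0 h, 177.6 ± 0.42 bp at 0.5 h, 179.7 bp in both libraries at 1 h and 184.8 ± 4.17 bp at 4 h (SD, n = 2). The exact permutation p over time was 0.019, and 0.21 after adjustment over 11 values, which no value could pass alone. The rise of the slope at 4 h came with first peaks at 162 bp in A and 132 bp in B, while the last of the 4 peaks lay at 697 and 690 bp, nearer than at 0 h. The difference from 0 h at 4 h was 8.0 bp with all fragments, 2.8 bp with 120 to 180 bp fragments and −1.45 bp with identical fragments counted once, so no change of spacing was established.

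At 0.5 h no 10 kb tile passed the threshold. The tile with the smallest p among those with more fragments was 3L 24020001 to 24030000, with a log2 difference from 0 h of 0.41 ± 0.08 (SE, n = 2 against 2), and among those with fewer it was X 1580001 to 1590000, at −0.45 ± 0.10 (−0.23 without the 0.5 h library A). The 6 higher tiles named by the rule ranged from 0.33 to 0.44 and the 6 lower ones from −0.52 to −0.34. Among 12773 tiles limma called 0, with 594 at an unadjusted p under 0.05 and a smallest adjusted p of 0.694. Chromosome 4 tiles had a median of 0.23 in A and 0.02 in B against the 0 h library of the same letter.

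At 1 h no tile passed either. The smallest p-values belonged to X 730001 to 740000, at 0.41 ± 0.11 (SE), and to 3L 14100001 to 14110000, at −0.39 ± 0.10. The 6 higher tiles ranged from 0.26 to 0.41 and the 6 lower ones from −1.09 to −0.28. Limma called 0 of 12773 tiles, with 269 at an unadjusted p under 0.05 and adjusted p-values of 1.00 for all 12 of these tiles. A and B had the same direction in 53.3% of tiles at 0.5 h, 48.6% at 1 h and 51.9% at 4 h.

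At 4 h no tile passed, though several lay close to the threshold. The fit shared 1 spread per tile over all times. The variance between libraries of 1 time beyond counting error, relative to the mean, was 0.00733 at 4 h. It was 0.000817 at 0 h, 0.0017 at 0.5 h and 0.00189 at 1 h. The p-values at 4 h may thus be too small, and those at 0.5 and 1 h too large. Among tiles with more fragments, 3 of the 6 smallest p-values were on chromosome 4. They were 680001 to 690000 with a log2 difference of 0.69 ± 0.11 (SE; 0.71 in A and 0.52 in B), 580001 to 590000 at 0.67 ± 0.11 and 370001 to 380000 at 0.66 ± 0.11. The others were X 7950001 to 7960000 at 0.82 ± 0.14, 3R 5160001 to 5170000 at 0.66 ± 0.12 and 2L 9170001 to 9180000 at 0.63 ± 0.12. Among tiles with fewer fragments, X 14120001 to 14130000 was at −0.77 ± 0.15, X 11010001 to 11020000 at −0.91 ± 0.19, 2R 730001 to 740000 at −1.07 ± 0.23, 2R 20300001 to 20310000 at −0.70 ± 0.15 and 2R 2170001 to 2180000 at −0.81 ± 0.18. Without the 4 h library A, 6 of the 12 tiles named at 4 h were smaller by over 1.5 times. They were X 11010001 at −0.32, 2R 2170001 at −0.26, X 14120001 at −0.42, 2R 20300001 at −0.39, 3R 5160001 at 0.39 and 370001 on chromosome 4 at 0.42. The tile 2L 22500001 to 22510000 held 2 fragments at 4 h against 141 at 0 h, a depth-scaled ratio of 0.195 (95% interval of counting error 0.0234 to 0.718). Limma called 0 of 12773 tiles, with 1816 (14.2%) at an unadjusted p under 0.05, and the adjusted p of the 12 tiles lay between 0.0521 and 0.106. That share was 4.65% at 0.5 h and 2.11% at 1 h. With only the 0 h and 4 h groups fitted by limma, the adjusted p was 0.154 for 2L 9170001 and 2L 22500001 and 0.184 for 2R 2170001.

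Chromosome 4 as a whole had a median log2 difference of 0.31 over 131 tiles at 4 h (fry p = 0.0441, adjusted p = 0.353; camera p = 0.099 with an estimated correlation, by limma). It was 0.43 in A and 0.06 in B. Without the 4 h library A the median was 0.07. Over all times together limma called 0 tiles, with 1683 at an unadjusted p under 0.05. The count at 4 h was not stable: it was 8 with identical fragments counted once and 33 without the 4 h library B. It was 157 in 1 kb tiles, where the called tiles held a median of 4 fragments in the 4 h library B and 22 in A, against 3 and 12 over all tiles tested.

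Across the genome the maps of 6 of the 8 libraries were close to each other whatever their time. The noise-corrected correlation in 1 kb bins was 0.994 between the 0 h libraries and 0.974 between the 1 h libraries. Libraries A at 0.5 h and at 4 h correlated at 0.962 with each other, while the 4 h pair correlated at 0.803 and the 0.5 h pair at 0.949. These values had identical fragments counted once. With all of them counted, the pairs at 0, 0.5, 1 and 4 h correlated at 0.986, 0.939, 0.959 and 0.759. Libraries A at 0.5 h and at 4 h then correlated at 0.937. The means that follow had identical fragments counted once. The mean over the 4 pairs of equal time was 0.930 and over all other pairs 0.928 (exact permutation p = 0.352 over 105 pairings).

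**Figure D3:**
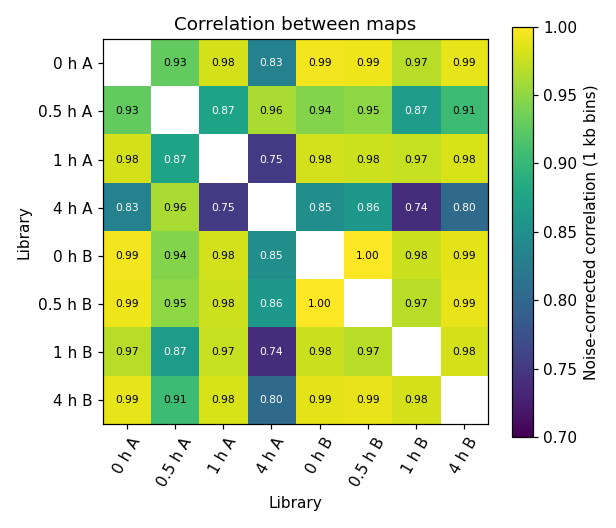
Noise-corrected correlation between the maps of all pairs of libraries in 1 kb bins, with libraries on both axes named by time in h and replicate. The 4 h library A has the lowest values, down to 0.740 with the 1 h library B, and its highest, 0.962, is with the 0.5 h library A.

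Fragment-poor gaps between nucleosomes were located on the arms and followed over time. There were 15893 gaps from the 0 h library B, measured in the A libraries, and 11592 from the 0 h library A, measured in the B libraries, with median widths of 148 and 146 bp. At 1 h the density of midpoints at gap centres was 0.644 of its 0 h value in A and 0.635 in B. At 0.5 h the ratio was 1.36 in A and 0.892 in B, and at 4 h it was 2.02 in A and 0.796 in B, the last from 90 midpoints. A and B followed the same course no more than other orders of the times did (exact permutation p = 0.333).

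**Figure D4:**
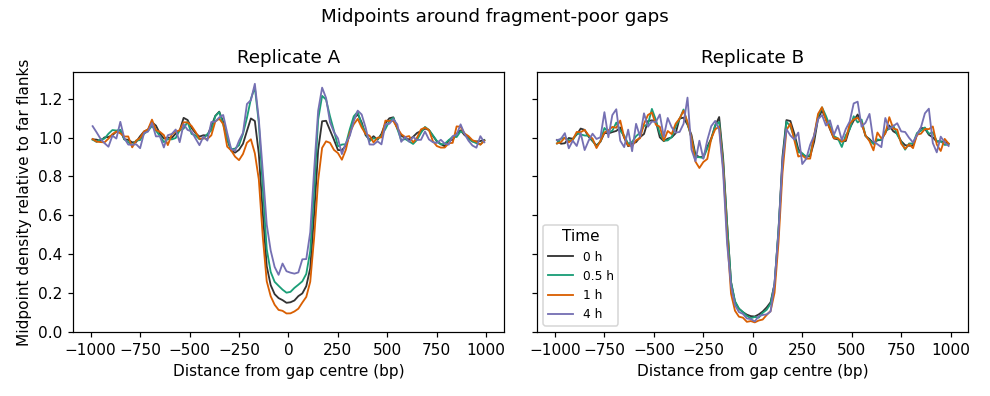
Density of midpoints of 120 to 180 bp fragments relative to the far flanks (y axis) by distance in bp from the centre of fragment-poor gaps (x axis), with 1 line per time and 1 panel per replicate. At the centre the 1 h line is the lowest in both panels, and the 4 h line is the highest in replicate A only.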

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

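All tests of explanations in this part were chosen after the results were seen. Of 33 comparisons between pairs of stimulated times over 11 values, 1 stood out because both libraries of 1 time lay below the 0 h mean and both of the other above it. It was the share of fragments on the mitochondrial genome, higher at 4 h than at 1 h by a mean of 1.32 percentage points. The difference was not tested, and most of it came from the 4 h library A, at 2.61%, against 0.201% in B.

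The A libraries at 0.5 h and 4 h stood apart from the other 6 and resembled each other. Their mutual correlation exceeded their mean correlation with the others by 0.104 with identical fragments counted once, which argues against repeated fragments as the source. The extent of digestion was not decided. The 4 h library A correlated at only 0.751 with the 1 h library A, whose median length was 120 bp against 121 bp. Median lengths within a gel-cut mononucleosomal band need not reflect digestion, and the share over 200 bp was 0.889% in the former and 4.37% in the latter. The A libraries at 0.5 h and 4 h were also the only ones with gap-centre density above their 0 h library, at ratios of 1.36 and 2.02. Those gaps were defined in the 0 h library B, with which these libraries correlated at 0.945 and 0.848. A map that departs from the 0 h maps can appear to fill such gaps, so the ratios are not an independent trait. A response to stimulation alone would need B to change as A did, and the slope of B on A was 0.0898 at 4 h and 0.126 at 0.5 h. The variance of the changes beyond counting error (× 10000) was 192 in A and 19.3 in B at 4 h, with a covariance of 17.2. At 0.5 h it was 59.9 in A and 6.81 in B, with a covariance of 7.55. B thus changed less than A, but the covariances were close to the variances in B. A smaller change shared by A and B is therefore not excluded. Uneven recovery of AT-rich DNA stays open: these were the highest 2 libraries in both of the 2 AT-rich shares, mitochondrial and chromosome 4, but also in the shares of the heterochromatin scaffolds and of XHet, and base composition was not measured.

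The density of 120 to 180 bp fragments at gap centres was lower at 1 h in both replicates, whereas for fragments of 44 to 90 bp the ratio to 0 h was 0.588 in A and 0.987 in B. The ratio in A was 0.668 with fragments of 140 to 160 bp, which argues against a shift of lengths within the nucleosomal class as the whole source, and 0.650 with identical fragments all counted, which argues against those. The contrast of the whole map, its coefficient of variation in 1 kb bins with counting error removed, was also highest at 1 h. It was 0.471 in A and 0.457 in B, against 0.418 and 0.412 at 0 h. Within each letter, times of higher contrast had lower gap levels, so a change local to gaps was not shown. Whether stimulation or a difference between single libraries lies behind the lower density cannot be told apart. With times exchanged within each letter, the mean level at 1 h was the lowest of 16 choices (one-sided exact permutation p = 0.0625, the smallest that 16 choices can give), for a time picked after its values were seen.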

How the results depend on the processing

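The 200 bp tiles, the omission of the mitochondrial tiles, the first version of the repeat length and all settings of the gap level were chosen after seeing the data. So was the tile fit that left out the A libraries at 0.5 h and 4 h together. Counts of called tiles were 0 in the chosen setting for every comparison. At 0.5 h the count was 1 with only the 2 groups compared, and at 1 h it was 14 in 200 bp tiles. At 4 h it was 8 with identical fragments counted once, 2 after thinning, 157 in 1 kb tiles, 353 in 200 bp tiles and 5 without mitochondrial tiles. Over time it was 3 with identical fragments counted once, 4 with 120 to 180 bp fragments, 2 after thinning, 876 in 1 kb tiles and 2293 in 200 bp tiles. Leaving out 1 library gave 0 to 33 tiles at 4 h (33 without the 4 h library B and 8 without the 0.5 h library B) and 0 to 11 over time. With the replicate block, 106 tiles passed at 4 h (72 higher, 34 lower), all 12 named 4 h tiles among them, and 218 over time. The labels do not say that a letter marks a shared culture or batch, and deviations of same-letter libraries correlated between −0.06 and 0.19, above 0.1 in 3 of 6 pairs of times, so a pairing was not established and is not excluded. None of the 16 named tiles changed direction in 318 values from 20 settings, of which 37 passed the threshold, but 6 of the 12 tiles at 4 h were smaller by over 1.5 times without the 4 h library A. The named tiles were picked for small p-values in these same libraries, and most settings refit the same counts. A kept direction is therefore no independent support. For all counts of tiles in this paragraph the cause was not tested.

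The 4 h repeat length moved from 8.0 bp above 0 h to −1.45 bp with identical fragments counted once and 2.8 bp with 120 to 180 bp fragments, and ranged from 5.05 to 10.95 bp when 1 library was left out. The first version gave 7.1 bp. On X alone and after thinning, not every library gave a repeat length, so those alternatives have no value. The heterochromatin share at 4 h moved to 1.09 points above 0 h with identical fragments counted once, a setting not independent of depth. Leaving out 1 library gave 0.0431 to 0.213 points for chromosome 4 at 4 h, 0.0284 to 2.44 points for the mitochondrial share at 4 h and −0.33 to 1.02 for the log2 gap level at 4 h, in each case depending on the 4 h library A. Correction for base composition, a count model and all promoter and gene list settings were not run. Depth was lowest in the 4 h library B, where the gap level rested on 90 midpoints and a 1 kb tile held a median of 3 fragments. At 4 h, 1816 tiles had an unadjusted p under 0.05, 387 without the 4 h library A and 2004 without B.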

Other observations

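The tests in this part were chosen after the data were seen. Across the 8 libraries the chromosome 4 share of the arm total and the log2 mitochondrial share had Pearson's r = 0.917 (exact permutation p = 0.0177) and Spearman's rho = 0.714 (exact permutation p = 0.0576). Without the libraries A at 1 h and 4 h, the farthest from the median mitochondrial share, r was 0.819 over 6 libraries. Without the A libraries at 0.5 h and 4 h, which stood apart in their maps, r was 0.188, so the relation rests on those libraries. This was the only relation of its kind computed.

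Changes from 0 h on the arms in 10 kb tiles were compared between A and B, each against its own 0 h library. The covariance (× 10000) was 7.55 ± 0.78 (bootstrap SE) at 0.5 h, −2.14 ± 0.75 at 1 h and 17.2 ± 3.37 at 4 h. Between different times, the 4 h change in A had a covariance of 21.3 ± 1.26 with the 0.5 h change in B and −19.5 ± 1.85 with the 1 h change in B, and the 0.5 h change in A had −12.9 ± 1.58 with the 1 h change in B. The mean over equal times was 7.54, and the highest of the other orders of the times gave 7.43, so equal times were not set apart. With 6 orders an exact permutation p cannot go below 0.167.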
